A study of Homo sapiens with 4 samples.

How the data were processed

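Polyadenylated RNA of the human glioblastoma cell line U87MG was sequenced in 4 libraries, 2 from populations that had invaded brain slices and 2 from poorly invasive control populations. Per the labels' protocols, parental cells were kept on organotypic brain slices for 1 week in neural stem cell medium with FGF and EGF. Invasive and control populations were then isolated and expanded in culture for 3 to 5 days before RNA extraction. Libraries were strand-specific mRNA libraries. The species of the slices is not given in the sources used here. The series' design text pairs each invasive population with a control of the same number, and calls the invasive populations independently derived. Each population is represented by 1 library. In the main test, which compares within pairs, p-values rest on how the difference between invasive and control populations varies between the pairs. Differences between culture dishes are part of that variation.

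The authors deposited 2 files per library. The raw files hold whole-number read counts per Ensembl gene, not normalized, per the file headers. Per the submitters' processing notes, bcl2fastq 1.8.4, TopHat2 2.0.12, Bowtie, HTSeq and DESeq2 were used with the GRCh38 build, with no role or order stated. Whether counting used the strand is not given in the sources used here, so antisense genes and genes with near-identical copies are treated as uncertain. The second file of each library holds a normalized value per gene that the authors rounded to whole numbers, a score whose normalization method is not given in the sources used here. Within a pair these scores have nearly the same sorted values: 85.3% of ranks were identical in pair 1 and 73.6% in pair 2. The score files of pair 1 list 32100 genes. Those of pair 2 list 10252, the genes with at least 200 raw counts over the pair. The scores were used in 1 alternative only.

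The raw files of pair 1 listed 32100 genes and those of pair 2 listed 33485. The 29387 genes present in all 4 were analysed. Genes listed for a single pair had at most 3 counts over pair 1 and 56 over pair 2, and were left out. Total counts were 17817756 in control 1, 15466900 in invasive 1, 15444104 in control 2 and 13829871 in invasive 2. A gene with no count in a library could have been present at up to 0.168 to 0.217 counts per 1e6 counts (CPM), the level of 3 counts, which covers counting error only.

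Genes were filtered with edgeR's filterByExpr by group (minimum count 10, minimum total 15), which left 14231. The main test was edgeR's quasi-likelihood F test, two-sided, with TMM factors, a robust prior, the pair as a block, and Benjamini-Hochberg adjustment at 0.05 (edgeR 4.0.16, limma 3.58.1, R 4.3.3). This design has 1 residual degree of freedom, so the spread of each gene leans on the prior estimated over all genes, worth 5.45 degrees of freedom. The biological coefficient of variation was 12.2%. The block follows the design text. As a check, the differences between libraries of the same group in pair 1 and pair 2 correlated across genes between the control and the invasive group (r 0.283), and the second principal component separated the pairs. Libraries of a group were not duplicates: the chi-square per degree of freedom was 34.1 between controls and 21.3 between invasive populations. The pair itself accounted for 14 genes past the threshold.

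On counts simulated from the means and library sizes of this comparison over 14231 genes, the blocked test recovered 33 of 50 genes raised by 1 log2 unit, 50 of 50 raised by 2, 21 of 50 lowered by 1 and 43 of 50 lowered by 2. It called 24 of 14031 unchanged genes. Set beside the recovered genes, these 24 made up a larger share of its calls than the adjusted threshold aims for. Calls in the data may therefore include more false ones than that threshold implies. The simulation also gave each gene a shift between pairs taken from the data. That shift favours the fit with the block, so the simulation does not measure what the block gains in the data. With no replicate block, 4 of 50 genes raised by 1 and 43 of 50 raised by 2 were recovered. That fit also recovered 4 of 50 lowered by 1 and 29 of 50 lowered by 2, and called 1 of 14031 unchanged genes.

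A set of 26 gene lists was fixed before the data were examined, and 23 had at least 5 tested members. Lists for neurons, oligodendrocytes and microglia had too few. Lists were tested with camera (preset correlation 0.01) in the blocked design, with camera's estimated correlation and fry as alternatives, and adjusted over the 23 lists. For single pairs, log2 differences of log2 CPM (prior count 2) were computed with no test. A list's median within a pair was placed among 10000 random lists of the same size matched on mean expression. The difference between the pairs' effects could not be tested, because that model leaves no residual degree of freedom.

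Named genes followed a rule fixed before the data were examined. It took up to 12 protein-coding genes per direction past the threshold, alike in direction in both pairs and with average log2 CPM of at least 1. Open places went to genes with values only. It also took the 4 members of each list with the largest fold changes. For other cell types it took the 3 marker genes with most counts, applied only to the tested astrocyte and endothelial lists. Last, it took the 5 genes per pair with the largest log2 difference in it among genes that differed in the other pair. These were under 0.5 in size or opposite in sign there. Y-linked genes that the rule picked are left out. Other called genes and list members were named after their values were seen.

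Alternatives were the fit with no replicate block, DESeq2 1.42.0, DESeq2 size factors, no filter, a filter of 1 CPM in all 4 libraries, other quasi-likelihood settings, limma-voom, leaving out each library in a fit with no block, a threshold of 0.1, prior counts of 0.5 and 8, and the authors' scores. Scaling by library totals only, and offsets for GC content and length with the block, were added after seeing the data. GC content and length came from the longest GENCODE 29 transcript and were known for 14095 of 14231 genes. Coordinates are those in the authors' files (GRCh38).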

Results

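The study asked which transcripts distinguish glioblastoma cells that invade brain tissue from cells that do not. U87MG is an established human glioblastoma line. Invasive populations were collected from organotypic brain slices, which are living sections of brain kept in culture. The 2 invasive populations and 2 poorly invasive controls each gave 1 mRNA library, with totals of 13829871 to 17817756 counts. Invasive 1 was compared with control 1 and invasive 2 with control 2. The first principal component (47.3% of the variance) placed the invasive libraries at 22.8 and 23.5 and the controls at −10.3 and −36.1. The second (35.0%) separated the pairs.

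Genes that rose in the invasive populations included a fibrillar collagen and 2 enzymes that cross-link collagen. COL1A1, a chain of type I collagen, rose from 459 ± 245 to 1158 ± 405 CPM (mean ± SD, n = 2 per group). LOXL1 and LOXL3, enzymes that cross-link collagen and elastin, rose by log2 fold changes of 1.37 ± 0.10 and 1.22 ± 0.11 (SE). HGF, which encodes the ligand of the MET receptor, had the largest log2 fall among the 5 called lower genes, from 39.0 ± 13.9 to 13.2 ± 3.92 CPM. HMGA1, an abundant chromatin protein, fell from 638 ± 167 to 347 ± 108 CPM.

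In total 34 genes rose and 5 fell among 14231 tested (edgeR quasi-likelihood test with the pair as a block, Benjamini-Hochberg adjusted p under 0.05), of which 33 and 4 were protein-coding. All 39 differed in the same direction in both pairs. The blocked test favours such genes, because disagreement between the pairs is its residual spread, so this agreement is no separate support. At an unadjusted p under 0.05, 1397 genes were higher and 1197 lower. Adjusted p-values lay close to the threshold, from 0.0205 to 0.05. With no replicate block the same test called 2 higher and 0 lower, and DESeq2 with the block called 142 and 29. Leaving out control 1, invasive 1, control 2 or invasive 2 gave 55, 22, 3 and 8 higher genes and 61, 3, 0 and 0 lower genes, in fits with no block.

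The largest increase among the named protein-coding genes was that of PADI2, which converts arginine residues of proteins to citrulline. It rose by a log2 fold change of 3.63 ± 0.28 (adjusted p = 0.0205), from 1.13 ± 1.05 to 13.6 ± 9.64 CPM. CRYAB, a small heat shock protein, rose by 2.98 ± 0.33 (adjusted p = 0.0401). Its levels were 1.53 ± 0.42 CPM in controls and 12.5 ± 4.00 CPM in invasive populations. STAC2, AK5 (an adenylate kinase), FIBCD1, ELFN2 and the chemokine gene CCL26 rose by 2.39, 2.34, 2.28, 2.27 and 2.07 log2 units. SYTL5, RASD2, the potassium channel subunit KCNE4, BEGAIN and the proteoglycan LUM rose by 2.07, 2.01, 1.97, 1.91 and 1.90. KCNE4 had 2.95 ± 0.14 CPM in controls (50 and 47 counts) and 11.6 ± 0.12 CPM in invasive populations (179 and 161 counts). With 2 libraries per group, so small a spread does not measure how closely its level repeats.

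Called genes outside that rule were chosen after their values were seen. They include NID2, a basement membrane protein (log2 fold change 1.05 ± 0.10), the fibrillar collagen COL5A2 (1.00 ± 0.11), PCOLCE2, which promotes procollagen processing (1.10 ± 0.13), and LEPREL1, a collagen prolyl hydroxylase (1.18 ± 0.14). SMAD6, an inhibitor of BMP signalling, rose by 0.95 ± 0.10. TUBA1A, an alpha tubulin, rose by 0.90 ± 0.09. The non-coding gene AC006262.5 (chromosome 19, 46189166 to 46203083) had the largest fold change of the 39, at 4.22 ± 0.29, with 9 and 10 counts in the controls and 146 and 174 in the invasive libraries. The current name of this gene marks it as antisense to IGFL2, and the strand setting of the counting is unknown. PSG4, which rose by 1.26 ± 0.16, belongs to a family of near-identical genes that can share reads.

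Besides HGF (log2 fold change −1.55 ± 0.13, adjusted p = 0.0205), the lower genes were the organic anion transporter SLCO4A1 (−1.50 ± 0.16), HMGA1 (−0.89 ± 0.10), the protease inhibitor SERPINB8 (−0.83 ± 0.10) and a pseudogene, AC005077.14, whose reads cannot be told from those of related copies with certainty. Several genes were lower in both pairs without passing the adjusted threshold. TFPI2, a matrix-associated protease inhibitor, averaged 1764 ± 1309 CPM in controls and 385 ± 104 CPM in invasive populations (log2 fold change −1.99 ± 0.35, adjusted p = 0.16). The inflammasome gene NLRP3 had −2.16 ± 0.32 (adjusted p = 0.0710). FGF14, L3MBTL4, DAW1, MAGEA1 and TMEM108 had log2 fold changes of −1.60, −1.44, −1.63, −1.80 and −1.44, with adjusted p-values from 0.0937 to 0.127.

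**Figure D1:**
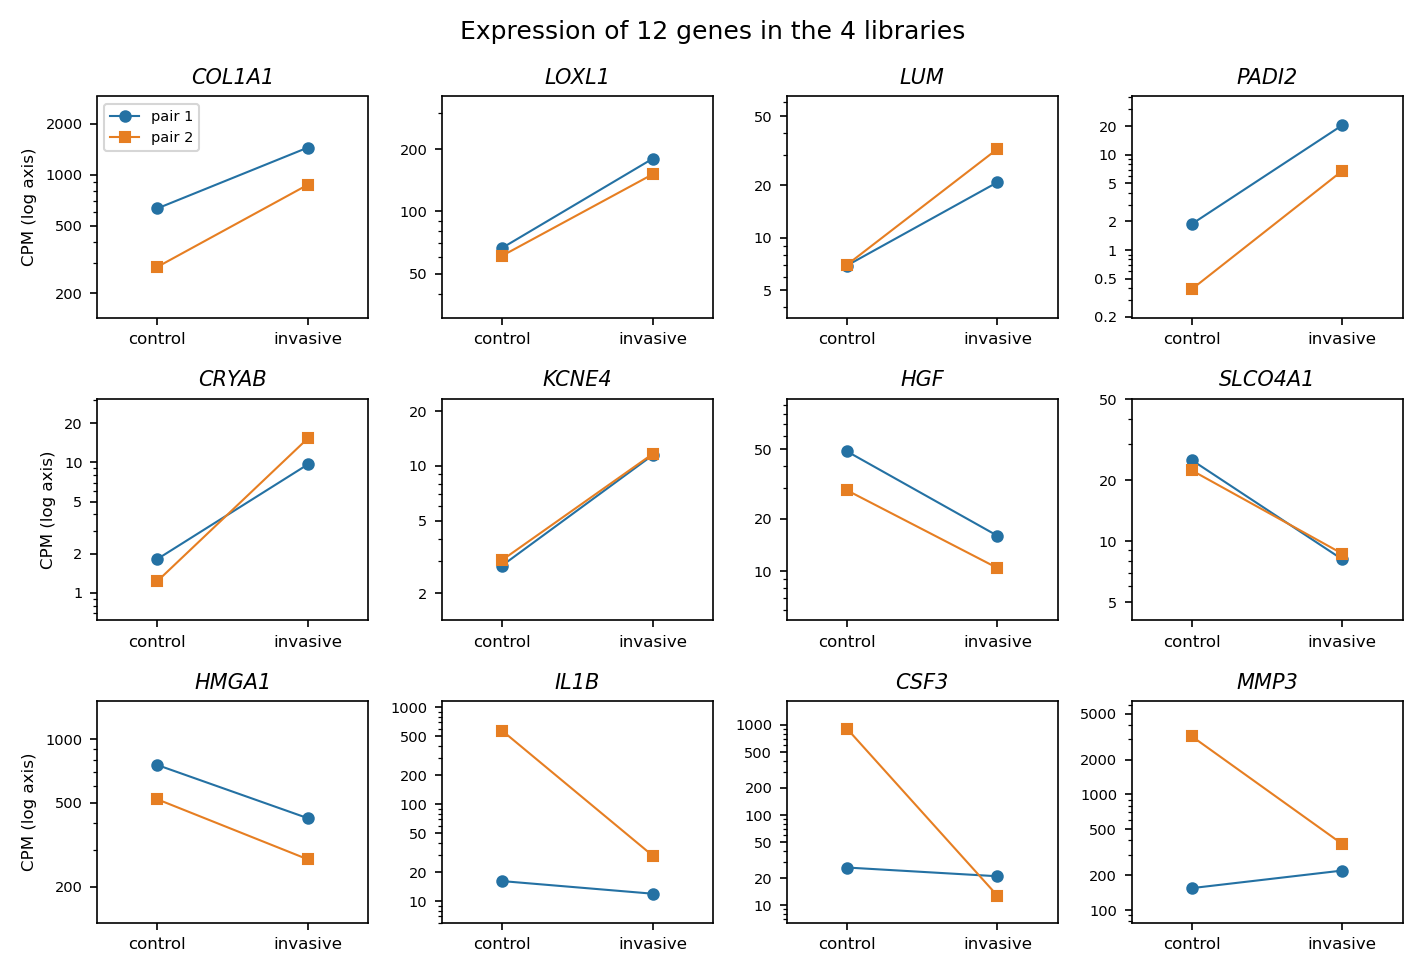
CPM (log axis) of 12 genes in the control and invasive library of each pair, with a line joining the libraries of a pair and 1 library per point. COL1A1, LOXL1, LUM, PADI2, CRYAB and KCNE4 were higher and HGF, SLCO4A1 and HMGA1 lower in both pairs, whereas IL1B, CSF3 and MMP3 were highest in control 2 (573, 908 and 3189 CPM).

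Genes were also examined as lists. Adjustment over a list alone, where given below, does not control error over all the genes named. In the main test 2594 of 14231 genes had an unadjusted p under 0.05. Of 23 lists, 10 passed the threshold with camera's preset correlation, 6 upward and 4 downward. The matrix, guidance, Wnt and FGF/EGF medians were extreme among random lists in both pairs (percentiles of at least 99.55 or at most 0.37). In pair 1 the contractile, stress, TGF-beta and YAP, and cell cycle medians lay at 96.25, 83.5, 83.82 and 7.58. The ribosomal median lay at 5.32 in pair 2. With an estimated correlation or with fry, 0 of the 23 lists passed. Both rest on the 1 residual degree of freedom of the blocked design, so they had little power to pass any list. The preset correlation is an assumption, so these alternatives neither uphold nor refute the calls. The matrix, Wnt and FGF/EGF lists passed in every fit that kept the preset correlation, including each one that left out a library. Those fits reuse the same libraries and the same assumed correlation, so this is not independent support.

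Extracellular matrix genes rose as a list, with a median log2 fold change of 0.81 over 21 members (adjusted p = 1.75e-13), but adjusted p = 0.896 with an estimated correlation. Of these genes, 15 were higher and 1 lower in both pairs. COL1A1, LUM and COL5A2 rose over all genes tested, and 9 rose when adjusted over the list alone: also COL4A1 (2.39 ± 0.47), COL5A1 (1.59 ± 0.34), COL1A2 (1.44 ± 0.18), SPARC (0.95 ± 0.14), COL4A2 and FBN1. COL4A1 had few counts, 16 and 8 in the controls and 43 and 72 in the invasive libraries. The change across the list was uneven. The type VI collagen chains COL6A1, COL6A2 and COL6A3 had log2 fold changes of 0.25, 0.08 and −0.01, and tenascin C (TNC) had −0.28. THBS1 had 1.61 ± 1.08, with a log2 difference of 0.39 in pair 1 and 2.94 in pair 2.

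Wnt pathway genes rose as a list (14 members, median 0.40, adjusted p = 0.000116), but adjusted p = 0.896 with an estimated correlation. None passed over all genes, and 6 rose when adjusted over the list alone. These were the receptors FZD7 (1.34 ± 0.20) and FZD2 (1.09 ± 0.19), the feedback inhibitors NOTUM (2.15 ± 0.39) and AXIN2 (1.06 ± 0.30), the transcription factor TCF7 (0.62 ± 0.11) and the ligand WNT5B (1.00 ± 0.28). The median was 0.79 without control 1 and 0.35 to 0.39 without any other library. WNT5A and FZD8 were lower in both pairs, with log2 fold changes of −0.25 and −0.42 that did not pass.

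Contractile and actin genes rose as a list of 19 (median 0.35, adjusted p = 0.00124), but adjusted p = 0.896 with an estimated correlation. Adjusted over the list alone, 4 rose: the myosin kinase MYLK (0.98 ± 0.15), the actin bundler FSCN1 (0.77 ± 0.12), RHOB and CNN2. CNN1 and ACTA2 had 0.92 ± 0.30 and 0.79 ± 0.43. The list's median was 0.05 in pair 1 and 0.45 in pair 2, and its call was lost without invasive 2 (median 0.16, adjusted p = 0.117). Without control 2 the median was 0.08.

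Axon guidance genes rose as a list of 22 (median 0.17, adjusted p = 0.0209), but adjusted p = 0.896 with an estimated correlation. Members moved both ways: adjusted over the list alone, 7 rose, among them EPHA3 (1.51 ± 0.34), NTN4 (1.21 ± 0.21) and EFNB1 (0.91 ± 0.23), and 2 fell, the netrin receptor DCC (−1.02 ± 0.25) and EFNB2 (−0.45 ± 0.11). The median was 0.44 without control 1. This call was lost without control 1, invasive 1 or control 2 (adjusted p = 0.165, 0.144 and 0.164) and with GC content and length offsets (0.11).

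The list of stress genes (unfolded protein and amino acid responses) rose with a median of 0.17 over 18 members (adjusted p = 0.0156), but adjusted p = 0.896 with an estimated correlation. No member passed over all genes or when adjusted over the list alone. CHAC1, HERPUD1 and DNAJB9 had 0.98 ± 0.24, 0.80 ± 0.26 and 0.77 ± 0.21. The median of the stress list was 0.03 in pair 1 and 0.305 in pair 2. TGF-beta and YAP targets rose with a median of 0.08 over 19 members (adjusted p = 0.0346), but adjusted p = 0.896 with an estimated correlation. Adjusted over the list alone, 5 rose, including ANKRD1 (1.51 ± 0.38), TGFBI (0.91 ± 0.22), AJUBA (0.84 ± 0.15) and CTGF (0.81 ± 0.17). The median of the TGF-beta and YAP list was 0.03 in pair 1 and 0.22 in pair 2. Without invasive 2 both lists had medians below 0 (−0.11 and −0.20), and without control 1 both calls were lost (adjusted p = 0.413 and 0.269). The stress list also missed the threshold with no replicate block (0.0562), and the TGF-beta and YAP list with GC content and length offsets (0.0673).

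FGF and EGF receptor pathway genes fell as a list, with a median of −0.29 over 20 members, of which 14 were lower and 1 higher in both pairs. Camera gave an adjusted p = 1.24e-05, and adjusted p = 0.896 with an estimated correlation. Adjusted over the list alone, 6 fell, all feedback regulators, targets or ligands of the pathway: ETV4 (−0.83 ± 0.14), HBEGF (−0.72 ± 0.12), DUSP6 (−0.64 ± 0.12), SPRED2 (−0.50 ± 0.11), SPRY2 and SPRY4. The receptor EGFR had −0.29 ± 0.13 and FGFR1 had −0.08 ± 0.15, and neither passed.

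Cell cycle genes fell as a list by a small amount (median −0.18). All 22 had negative fold changes and 17 were lower in both pairs, yet none passed when adjusted over the list alone. Camera gave an adjusted p = 0.00124, and adjusted p = 0.896 with an estimated correlation. Its median was −0.02 without invasive 2, −0.08 without control 1 and −0.40 without invasive 1. MCM7, BUB1, AURKB and CCNA2 had −0.34, −0.33, −0.33 and −0.31. Ribosomal protein genes fell as a list (median −0.16), with 25 of 26 lower in both pairs and none past the threshold adjusted over the list alone. Camera gave an adjusted p = 0.00507, and adjusted p = 0.896 with an estimated correlation. Its median was −0.25 without control 2 and −0.11 without control 1. RPL5, RPS18, RPL11 and RPS6 had −0.31, −0.29, −0.29 and −0.29. Both calls were lost without control 1 (adjusted p = 0.344 and 0.191) and without invasive 2 (0.817 and 0.113).

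Inflammatory cytokine genes passed the test downward (median −0.88 over 18 members), but the pairs differed in direction. Camera gave an adjusted p = 0.0105, and adjusted p = 0.896 with an estimated correlation. No member passed over all genes or when adjusted over the list alone. The median log2 difference was 0.42 in pair 1 and −2.31 in pair 2. Without control 2 the median was 0.62 (adjusted p = 3.44e-06, upward), and without invasive 1 the call was lost (adjusted p = 0.292).

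The other 13 lists did not pass. In fits that left out a library, 3 of them passed downward: mesenchymal and sterol genes without control 1 (adjusted p = 0.0189 and 0.0072) and hypoxia genes without control 2 (0.0395). Integrin, protease, interferon, Notch, sterol, immediate early and mitochondrially encoded genes had medians from −0.03 to 0.11. Mesenchymal and proneural glioblastoma genes had −0.12 and 0.04. Hypoxia, epithelial to mesenchymal transition, astrocyte and endothelial genes had 0.00, 0.16, 0.09 and 0.00. Within these lists some members passed when adjusted over the list alone. PDGFRA, the PDGF receptor of the proneural class, rose (1.33 ± 0.28). The cadherin CDH11 fell (−1.19 ± 0.24), as did the angiogenic factor VEGFA (−0.58 ± 0.11) and the protease inhibitor TIMP1 (−0.56 ± 0.13). In the protease list 2 rose, MMP2 (0.51 ± 0.11) and SERPINE2 (0.47 ± 0.10), and 2 fell, TIMP1 and PLAUR. TIMP1 is also in the mesenchymal list, where it did not pass. ITGA10 rose (1.02 ± 0.17) and ITGA7 fell (−0.43 ± 0.10). The interferon genes IFI6 (0.78 ± 0.20) and OAS1 (−1.54 ± 0.41) moved in opposite directions.

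**Figure D2:**
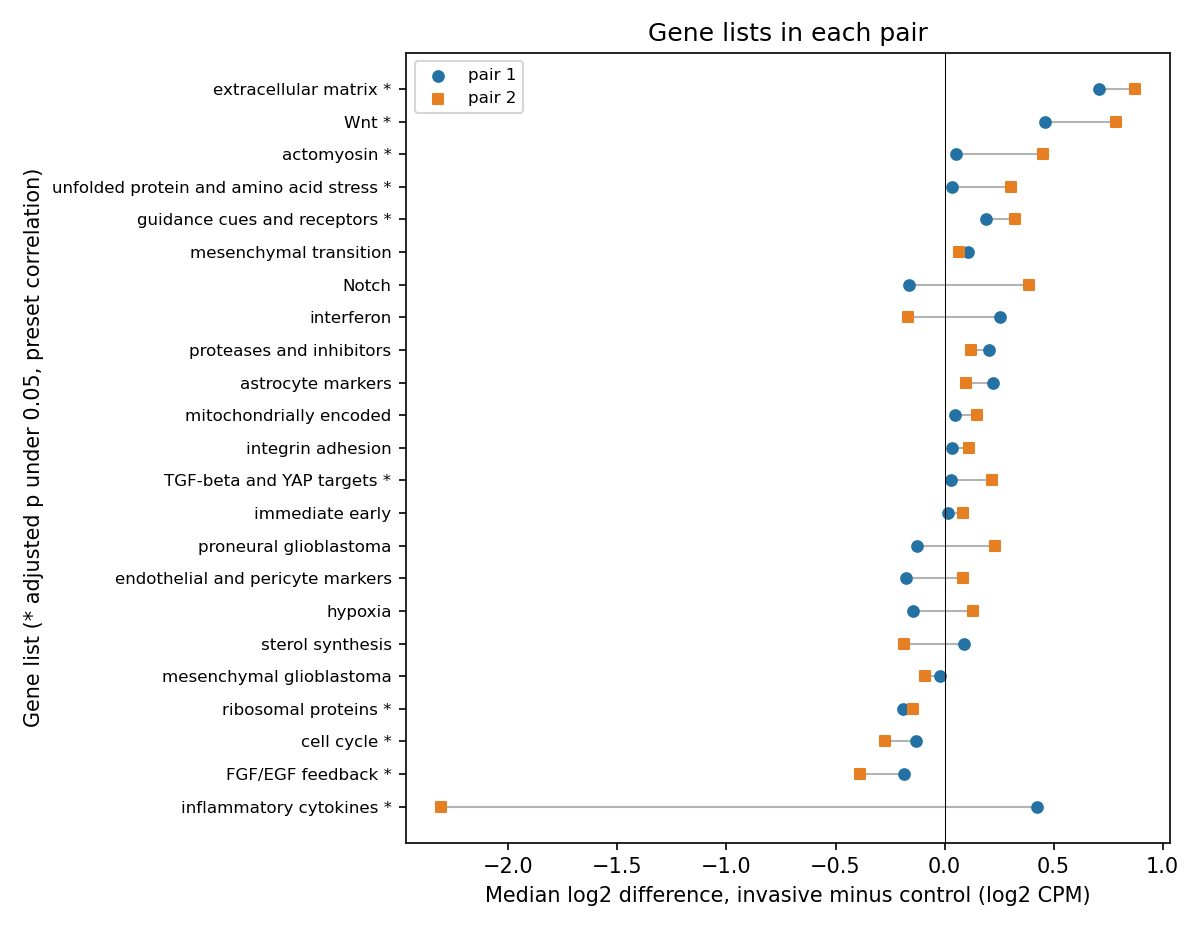
Median log2 difference (invasive minus control, log2 CPM) of the members of each of 23 gene lists in pair 1 (circles) and pair 2 (squares), with 1 library against 1 in each pair. The matrix list had 0.71 and 0.88, and the inflammatory list had 0.42 and −2.31. Asterisks mark the 10 lists past the threshold with the preset correlation, none of which passed with an estimated correlation.

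Brain slices contain other cell types, and many of their markers had few or no counts, while others are expressed at high levels in these libraries. PTPRC, a leukocyte gene, had 1, 1, 0 and 1 counts in control 1, invasive 1, control 2 and invasive 2. AQP4 of astrocytes, MOG of oligodendrocytes, CLDN5 of endothelium and P2RY12 of microglia had 0 in each. The species of the slices is not given, so these counts do not measure cells whose reads fail to map to the human genome. The astrocyte genes CLU and GJA1 had at least 6123 and 2967 counts in each library. The oligodendrocyte gene CNP and the neuron gene SNAP25 had at least 1229 and 364. CLU, GJA1 and the pericyte gene PDGFRB had log2 fold changes of 0.09 ± 0.12, 0.08 ± 0.14 and 0.23 ± 0.12. CSPG4 and KDR had −0.33 ± 0.09 and −0.79 ± 0.32. TMEM119, in the microglia list but also expressed by bone-forming cells, was higher in both invasive populations without passing the threshold (1.95 ± 0.39, adjusted p = 0.117), while CSF1R and CD74 of the same list were not higher in both. CD68, with 21 to 38 counts, was also higher in both without passing (0.64 ± 0.35, adjusted p = 0.385).

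The pairs were also compared with each other, to ask whether independently derived invasive populations differ from their controls in like ways. They share no library. Across 14231 genes the log2 differences of the pairs correlated (Spearman's rho 0.395, Pearson's r 0.387), and 65.3% had the same sign. Genes are not independent replicates, so these values carry no p. At least 2-fold, 430 genes were higher and 138 lower in pair 1, and 614 and 294 in pair 2. Of these, 164 were higher in both, against 18.6 for independent lists, and 26 were lower in both, against 2.85. Another 27 differed 2-fold or more in opposite directions, also more than independent lists would give. Independence treats all tested genes as equally likely to reach 2-fold, so these excesses need not all reflect likeness between the pairs. Each pair has 1 library per group, so counts within a pair have no replicate check. With the authors' normalized values, which cover 10252 genes and used a pseudocount of 1, the genes 2-fold different the same way in both pairs numbered 43 in place of 190, and with no filter rho was 0.198.

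**Figure D3:**
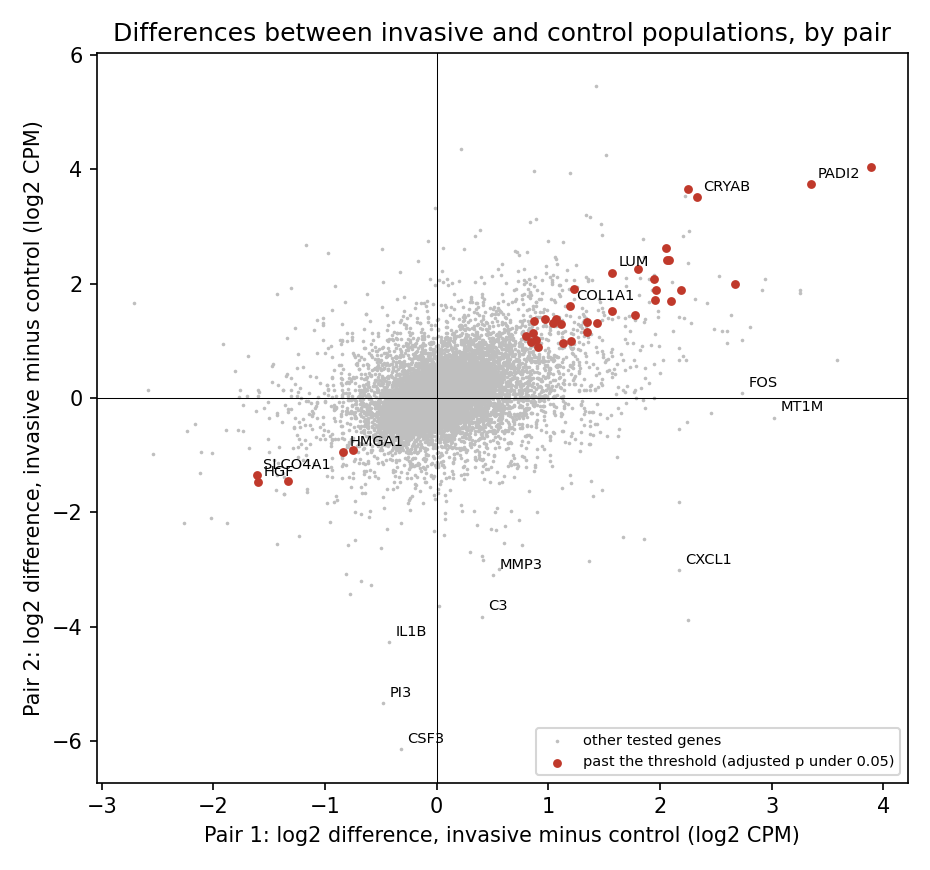
Log2 difference (invasive minus control, log2 CPM with a prior count of 2) of each tested gene in pair 1 (horizontal) and pair 2 (vertical), with the genes past the adjusted threshold in red. All 39 called genes lie in the quadrants where the pairs have the same sign, which the blocked test favours. CSF3, IL1B and PI3 had differences of −6.14, −4.27 and −5.33 in pair 2 and −0.32, −0.43 and −0.48 in pair 1.

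Genes that differed in pair 2 but not in pair 1 were led by secreted inflammatory factors, all high in control 2. CSF3, the granulocyte growth factor, had 908 CPM in control 2 against 12.7 in invasive 2, and 26.2 against 20.9 in pair 1. IL1B had 573 CPM in control 2 and 12.0 to 29.6 CPM in the other libraries. Complement C3 had 804 CPM and the matrix protease MMP3 had 3189 CPM in control 2, against at most 56.7 and 373 elsewhere. The protease inhibitor PI3 had 42.9 CPM in control 2 and under 1 CPM elsewhere. In pair 1, FOS, an immediate early transcription factor, had 32.6 CPM in invasive 1 and 4.78 in control 1, and the metallothionein MT1M had 8.33 and 0.91 CPM. Their log2 differences in pair 2 were 0.09 and −0.34. CH25H, which makes 25-hydroxycholesterol, had 4.80 CPM in invasive 1 and 0.97 in control 1, and the opposite order in pair 2 (3.33 and 4.93 CPM). The medians of the interferon and sterol lists lay high among random lists in pair 1 (percentiles 98.7 and 98.0) and low in pair 2 (2.33 and 2.12). Those of the hypoxia and Notch lists lay low in pair 1 (3.82 and 5.9) and high in pair 2 (97.0 and 97.0). None of these differences between the pairs could be tested.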

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

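The tests of GC content and of fibroblast or pericyte transcripts for the matrix genes, and of leukocyte transcripts for the cytokine genes, were chosen after the result was seen. The leukocyte test first used the counts of PTPRC, CX3CR1 and P2RY12 and was rewritten with more abundant transcripts once values had been seen. The cytokine list, CXCL1 and MMP12 stood out because the pairs moved in opposite directions. The differences between the pairs were not tested, since each pair has 1 library per group.

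The inflammatory cytokine list had a median log2 difference of 0.422 in pair 1 and −2.31 in pair 2, and pair 2 minus pair 1 was −2.73. CXCL1 differed between the pairs by −5.18 and the macrophage elastase MMP12 by −3.98, pair 2 minus pair 1. In pair 1 these 2 genes had 2 and 3 counts in the control, and their ratios of invasive to control were 8.44 (exact 95% interval 1.96 to 76.1) and 7.13 (2.1 to 37.6), counting error only.

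The large fall of the cytokine list in pair 2 lies in control 2, where IL1B had 573 CPM and IL6 53.5 CPM. Its rise in pair 1 (median log2 difference 0.422) does not involve control 2, and the source of that rise was not tested. Leukocytes from the slice would bring their abundant transcripts. LAPTM5, CD53, ITGB2, FCER1G and PTPRC had 32, 6, 2, 13 and 0 counts in control 2, and the largest gain over control 1 among them was 0.0867% of the IL1B gain in CPM, which argues against leukocytes as the source if their reads map to the human genome (the species of the slices is not given). A distortion of the whole library would move other lists too, but the largest median shift of another list between control 2 and control 1 was 0.961 in size (proneural genes), against 2.84 for the cytokine list. A cytokine response of the U87 cells in that culture stays open as a hypothesis, as does a state of the poorly invasive population itself, and 1 library does not separate them.

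Of 21 matrix genes, 15 were higher in both invasive populations and 1 was lower in both. Correcting GC content and transcript length left the list's median at 0.767, close to 0.805 without the correction, so a bias of that kind does not account for its size. The list's call has adjusted p = 0.896 with an estimated correlation in the uncorrected fit. Fibroblasts or pericytes carried over from the slice would bring COL3A1 and DCN along with COL1A1, yet the largest gain of either was 0.157% of the COL1A1 gain in CPM, which argues against such cells if their reads map to the human genome. Among POSTN, PDGFRB and RGS5, also checked, PDGFRB had the largest gains, 0.708% in pair 1 and 0.551% in pair 2. A difference in matrix production may underlie the pattern, as a hypothesis, and effects of growth or density during the expansion of 3 to 5 days were not tested.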

How the results depend on the processing

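Scaling by library totals and offsets for GC content and length were chosen after seeing the data. All 39 called genes had the same direction in each of the 15 alternative fits, of which 1 (1 CPM in all libraries) tested 35 of them. These fits reuse the same libraries, so this is not independent support. Counts of calls moved widely. Adjusted p-values crowd the threshold, and the prior also differs with the scaling (5.45 degrees of freedom with TMM, 6.36 with DESeq2 size factors, 10.4 with library totals).

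Against 34 higher and 5 lower genes, the fit with no replicate block called 2 and 0, DESeq2 with the block 142 and 29, DESeq2 without it 143 and 37, DESeq2 size factors 80 and 9, no filter 760 and 693, the 1 CPM filter 12 and 2, library totals 368 and 91, and a threshold of 0.1 called 205 and 47. Leaving out each library gave 3 to 55 higher and 0 to 61 lower genes. Fits with the robust prior off, bias-adjusted quasi-likelihood, limma-voom or GC content and length offsets stayed within 1.5 times.

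Against 10 lists, an estimated correlation and fry gave 0, and leaving out each library gave 5 to 10. Leaving out each library moved the cytokine median from −2.45 to 0.619, with the direction turned without control 2. Stress genes ranged from −0.11 to 0.423 and TGF-beta and YAP targets from −0.196 to 0.334, both turned without invasive 2. Fits without a library have no block, since its pair is broken. A fit of the difference between pairs cannot be run.

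Against 568 genes 2-fold different in pair 1, 908 in pair 2 and 190 in both, a prior count of 8 gave 316 in pair 1 and 117 in both. The authors' scores gave 88, 316 and 43, the 1 CPM filter 231, 513 and 90, and no filter 2067, 2972 and 410, with rho at 0.198. Filters and the authors' scores change the genes compared, and the scores also came with another pseudocount. The cause was not tested.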

Other observations

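Further gene groups were higher in both pairs, by different amounts. They were noticed in the table of all genes and then tested with camera on the same data, so they are hypotheses. Enzymes and chaperones that process collagen had a median log2 fold change of 0.47 over 22 genes, with 17 higher and 0 lower in both pairs and medians of 0.20 in pair 1 and 0.73 in pair 2 (p = 7.38e-18, and p = 0.168 with an estimated correlation). LOXL1, LOXL3, PCOLCE2 and LEPREL1 passed over all genes. The collagen chaperone SERPINH1 and the propeptidase ADAMTS14 had 0.81 ± 0.11 and 2.45 ± 0.31 without passing (adjusted p = 0.0567 and 0.0504). Targets of the aryl hydrocarbon receptor were higher in both pairs for 5 of 5 genes, with medians of 0.78 and 1.34 (p = 7.59e-09, and p = 0.231 with an estimated correlation). Among them AHRR rose by 0.94 ± 0.12, and CYP1B1 and CYP1A1 had 0.97 ± 0.13 and 2.03 ± 0.48 without passing. The 5 tested PSG genes were all higher in both pairs (median 1.26, p = 2.64e-06, and p = 0.174 with an estimated correlation), but these near-identical genes can share reads.

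Lower ribosomal protein genes raised the hypothesis that ribosome production genes were lower in general. A list of 25 nucleolar and ribosome biogenesis genes, none examined before, was tested with the prediction written first. A test of GC content and length for the ribosomal protein genes was dropped from the predictions, and in that fit their median was −0.147 (adjusted p = 0.00876). Uncorrected, the ribosomal list has adjusted p = 0.896 with an estimated correlation, and its call was lost without control 1 (0.191) and without invasive 2 (0.113). The biogenesis list had a median log2 difference of −0.31 in pair 1 and −0.32 in pair 2, with 22 genes lower and 1 higher in both (camera p = 8.19e-10, and p = 0.0924 with an estimated correlation). NCL, NPM1, NOLC1, WDR43 and UTP20 had log2 fold changes of −0.46, −0.44, −0.49, −0.54 and −0.50, and 0 of the 25 passed over all genes. The result is consistent with slower ribosome production in the invasive populations, as a hypothesis only, since transcript levels do not measure that rate.

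Populations derived from a cell line may differ in chromosome content. Median log2 differences were computed over windows of 20 Mb with at least 20 genes on the autosomes and X, and the prediction was written before the test, whereas the regions named below were drawn from its result. In pair 1 the largest absolute median among 151 windows was 0.333, and 6 windows exceeded 0.182, the 95th percentile of the largest median over 1000 shuffles of gene positions. In pair 2 the largest was 0.198 and 0 windows exceeded the corresponding 0.237. Of the 6 windows, 2 lay on chromosome 18 (−0.33 and −0.31), 2 on chromosome 14 (0.25 and 0.25), 1 on chromosome 13 (−0.22) and 1 on chromosome 4 (−0.20). Along chromosome 18 from 41955206 to 80147523, 88.8% of 80 genes were lower in invasive 1 than in control 1 (median −0.31). Along chromosome 14, 78.4% of 379 genes were higher (median 0.18).

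A candidate explanation for the regional shifts of pair 1 is that a share of its invasive or control cells carried another copy number on chromosome 18, where the windows passed the size of 0.3 set beforehand, and possibly on chromosome 14, where they did not. After removal of the trend with GC content and length the largest window median was 0.356 in size, and the windows on chromosomes 18 (−0.36 and −0.28) and 14 (0.29 and 0.19) stayed beyond the shuffles (0.169), whereas those on chromosomes 13 (−0.14) and 4 (−0.08) did not. Against the mean of the pair 2 libraries, the chromosome 18 region was lower in invasive 1 (−0.19) and higher in control 1 (0.17), and the chromosome 14 region was higher in invasive 1 (0.11) and lower in control 1 (−0.05), so which population changed stays open.

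In pair 2 the regions had medians of 0.03 on chromosome 14 and −0.11 on chromosome 18. Of the 39 called genes, 3 lie in these regions, NID2, BEGAIN and SERPINB8. Each differed in the same direction in pair 2, as did all 39, which the blocked test favours. That agreement therefore does not show whether the regional shifts contributed to these 3 calls. Regional regulation of transcription was not tested and cannot be separated from copy number without DNA.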
